A study of Mus musculus with 4 samples.

How the data were processed

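RNA was measured by sequencing in 4 libraries of cultured mouse liver cells, 2 from progenitor-like cells grown out of hepatocytes (HepLPC) and 2 from progenitor-like cells grown out of the non-parenchymal fraction of the liver (NPC_LPC). Per the labels' protocols, total RNA was isolated with a column kit and paired-end libraries were made from polyadenylated RNA with a kit that keeps the strand. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq, with the genome build mm10. Versions, the gene annotation and the strand setting of the counting are not given in the sources used here.

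Each library had 1 deposited table with a count and an FPKM value for every gene symbol. Per the file headers, the authors gave read counts per gene. The deposited counts were whole numbers with a different total in each library. Per the file headers, the authors also gave FPKM, fragment counts scaled by transcript length and library size. The counts were used for all main results, and the FPKM only as alternatives. The tables held 21878 rows in the same order, of which 6043 had no count in any library. A few rows carry symbols that a spreadsheet turned into dates. They were kept in the library totals and the tests, and none is named. Gene positions were taken from a RefSeq table on the same mouse assembly (GRCm38, the assembly called mm10), which matched 21318 rows, or 97.4%, by symbol or by an unambiguous older symbol. A library's group and replicate number were read from its title. The label of cell type for HepLPC mentions both hepatocytes and non-parenchymal cells, so the titles and the protocol decided the grouping.

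The total count ran from 17575998 to 20625957 per library. A count of 3, the floor used for a gene with no count, equals between 0.149 and 0.169 CPM (counts scaled to a common library size). Floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. CPM values use the library totals multiplied by TMM factors, which lay between 0.98 and 1.02.

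Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 after TMM normalization and filterByExpr, which left 12332 genes. Group was the only term, and fold changes are HepLPC over NPC_LPC on the log2 scale. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Standard errors of log2 fold changes were derived from the F statistic. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333, so no such test was run. Nothing in the labels says that replicates came from separate mice or cultures, so the p-values of the gene tests measure only the spread between these libraries. Each library was counted as a replicate because its title gives it a replicate number.

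Before the data were examined, 31 gene lists, the rule for named genes, the tests and most alternatives were fixed. Lists with at least 5 tested members (25 lists) were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera compares a list with the other genes. Its p-values were adjusted over the lists. Each list was tested again with an estimated correlation and with fry. The edgeR p-values of a list's members were also adjusted over the list alone, which was not among the fixed tests. That adjustment is usually more lenient than the one over all genes and takes no account of correlation between members. Genes were named by 3 parts of a rule. The first part is 13 cell identity genes. The second is the 8 genes higher and the 8 lower with the largest absolute log2 fold change among those past the threshold, with a mean CPM of at least 5 and groups that do not overlap, predicted genes left out. The third is up to 3 members of each list past the threshold with the smallest p, or the 2 most abundant members where none passed. Other genes named were chosen after their values were seen.

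The alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, leaving out the 20 most abundant genes, a threshold of 0.01, a minimum fold of 1.5, and limma on log2 FPKM with several pseudocounts and filters. Chosen after seeing the data were limma on log2(FPKM + 1) for genes with a mean of at least 0.5, an edgeR fit without the chromosome medians described in the results, and the analysis of those medians itself. That analysis used 8824 genes with a position and a mean log2 CPM above that of 10 CPM. Each chromosome was cut into 6 bins of equal gene number, and the mean of its bin medians was set against 100000 random draws of 6 bins from the whole genome (a permutation test, two-sided, Benjamini-Hochberg adjusted over 60 chromosome and comparison pairs). The p-values of that test measure the spread between bins within a comparison, not the spread between libraries. GC content and transcript length came from the GENCODE transcripts of the same assembly and were found for 99.9% of these genes.

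The steps were tested on simulated counts for the 12332 genes of this comparison, with 200 changed genes. Means and library sizes were those of the real data. Dispersions were drawn at random around the trend of the real data, with a spread taken from the edgeR fit, so no gene kept its own dispersion. The edgeR test called 49 of 100 genes changed 16-fold, 0 of 100 genes changed 4-fold and 4 unchanged genes. DESeq2 called 98 and 63 of these genes and 171 unchanged genes. A list shifted in the simulation was the only list called by camera, and a chromosome shifted 1.5-fold gave a median log2 ratio of 0.53. The simulated genes were drawn independently, so calls of lists with correlated members were not tested. In the real data the estimated correlation was 0.623 for the interferon response list and 0.783 for the cell cycle list. The shares of genes called apply to a simulation with 200 changed genes and these drawn dispersions. Because their spread came from the edgeR fit, they do not rank edgeR against DESeq2 on the real data.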

Results

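The libraries profiled mouse liver progenitor-like cells, a proliferating state that adult liver cells take on when they are cultured in transition and expansion media. Per the labels the mice were C57BL/6 and 6 to 8 weeks old. The protocol describes lineage-tracing mice in which hepatocytes or their descendants carry a fluorescent mark: tdTomato mice given a hepatocyte-directed Cre virus, and AlbCreERT/R26GFP mice, listed respectively for the hepatocyte and the non-parenchymal preparations. The series compared the expression profiles of cells of hepatocyte origin (HepLPC, n = 2 libraries) with those of non-parenchymal origin (NPC_LPC, n = 2 libraries). If the mice were used as listed, mouse line and virus treatment follow the group. Differences between the origins, for genes and lists alike, then cannot be separated from them, and origin below names the group only. Total counts were 18123118 and 17575998 for HepLPC replicates 1 and 2, and 17919947 and 20625957 for NPC_LPC replicates 1 and 2. Between 14070 and 14333 genes had at least 1 count in a library. Values below are CPM as mean ± SD of the 2 libraries of a group unless a library is named.

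Libraries of the same origin resembled each other more than libraries of different origin. Across the 12332 tested genes, Pearson's r of log2 CPM was 0.947 between the HepLPC libraries and 0.934 between the NPC_LPC libraries. The 4 pairs of different origin had r between 0.854 and 0.873. The main principal component separated the origins and held 64.6% of the variance. Genes are not independent replicates, and these values describe the libraries without a test.

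Both kinds of culture expressed keratin genes and Vim, and hepatocyte secreted protein genes differed widely in level, from Alb near the floor to an abundant Apob. Apob, the apolipoprotein B gene, was at 3456 and 4726 CPM in HepLPC replicates 1 and 2 and at 2654 and 1471 CPM in those of NPC_LPC, and the transferrin gene Trf was at 203 to 727 CPM in the 4 libraries. Alb, the albumin gene and the most abundant transcript of mature hepatocytes (chromosome 5, 90460870 to 90476602), was at 2.28 CPM in HepLPC replicate 1 and at or below 0.149 CPM in the other 3 libraries, where it had at most 3 counts. Afp, a fetal liver protein, was at 4.001 and 4.57 CPM in HepLPC replicates 1 and 2 and at 0.439 and 7.23 CPM in those of NPC_LPC. The intermediate filament gene Vim was abundant in both, at 2077 ± 120 CPM in HepLPC and 1694 ± 245 in NPC_LPC. The proliferation marker Mki67 was at 381 to 837 CPM in the HepLPC libraries and at 344 to 617 in the NPC_LPC libraries. Sox9, a biliary and progenitor transcription factor, was at 112 ± 4.44 CPM and 169 ± 123 CPM in HepLPC and NPC_LPC. Epcam, a surface protein of bile duct cells, stayed at or below 1.75 CPM in all 4 libraries. The fibroblast collagen gene Col1a1 was at 2.93 ± 1.59 CPM in HepLPC and 7.27 ± 6.40 in NPC_LPC. The endothelial gene Pecam1 and the leukocyte gene Ptprc had at most 1 and 5 counts in any library. Alb, Pecam1 and Ptprc were too low for the edgeR test, and none of the other cell identity genes passed it between the origins. Hnf4a was the closest at an edgeR adjusted p of 0.057, while DESeq2 called Hnf4a, Krt19 and Cdh1 higher in HepLPC (adjusted p = 7.05e-10, 6.2e-06 and 0.0487). The hepatocyte transcription factor Hnf4a (chromosome 2, 163506811 to 163572907) was at 242 ± 10.1 CPM in HepLPC and 38.6 ± 15.9 in NPC_LPC, a log2 fold change of 2.65 (SE 0.35). The biliary keratin Krt19 was at 1160 ± 389 CPM in HepLPC and 193 ± 116 in NPC_LPC, with an adjusted p of 0.0841 in the edgeR test. Krt7, on chromosome 15, was at 134 ± 44.1 CPM and 9.33 ± 11.2 CPM, and Cdh1, the epithelial cadherin, at 802 ± 0.547 CPM and 264 ± 224 CPM, with edgeR adjusted p of 0.132 and 0.22.

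**Figure D1:**
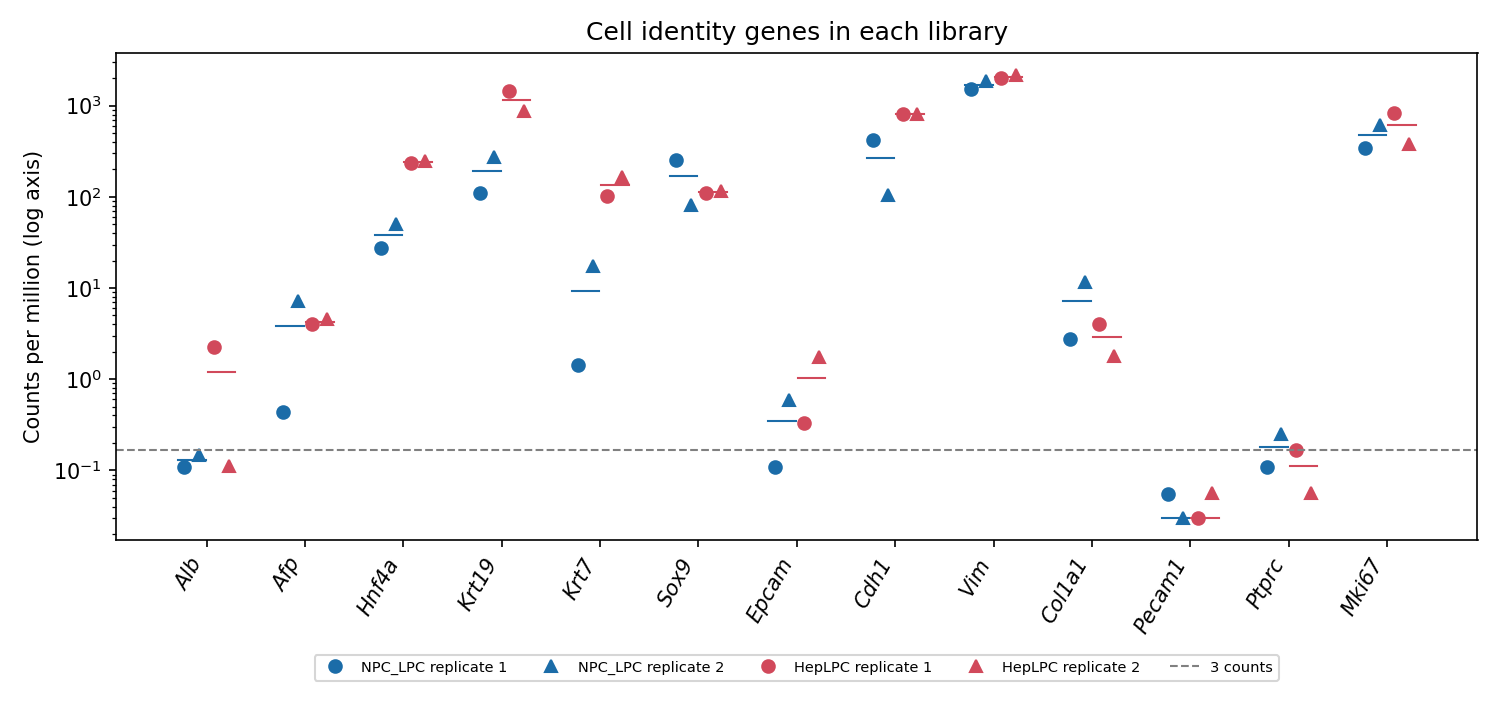
CPM of the 13 cell identity genes (log axis) in each of the 4 libraries, with circles for replicate 1, triangles for replicate 2, short lines for group means and a dashed line for the highest mean floor of 3 counts; a value of 0 is drawn at 0.03. Hnf4a, Krt19 and Krt7 lie higher in both HepLPC libraries than in both NPC_LPC libraries, and Pecam1 and Ptprc lie near or under the floor in all libraries.

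The edgeR test called 53 genes between the origins. Of these, 28 rose in HepLPC and 25 fell, and all 53 differed at least 2-fold, the smallest by 1.95 on the log2 scale. Among the genes that rose were Lgals2, a galectin of gastrointestinal epithelium (chromosome 15, 78850860 to 78855529), at 593 ± 87.2 CPM against 8.18 ± 0.00313 CPM, which is 72.5-fold higher (log2 fold change 6.18, SE 0.31, edgeR adjusted p = 0.0194). Cdhr5, a cadherin of the brush border (chromosome 7), and Ddc, the aromatic amino acid decarboxylase (chromosome 11), had no count in either NPC_LPC library and were at least 134-fold and 132-fold higher in HepLPC against a floor of 3 counts per library. Cpne4 (chromosome 9) rose 111-fold, Gcnt3 (chromosome 9), a mucin-modifying glycosyltransferase, 80.7-fold, and Clic5 (chromosome 17) 79.2-fold, from NPC_LPC levels at or below 0.384 CPM. Fgfbp1 (chromosome 5) and Pkhd1l1 (chromosome 15) rose 57.4-fold and 50.6-fold. In HepLPC replicates 1 and 2, Fgfbp1 was at 58.6 and 23.1 CPM and Pkhd1l1 at 13.7 and 21.4 CPM.

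The 8 genes named for the largest falls in HepLPC include 3 interferon-induced genes. Piezo2, a mechanically gated ion channel (chromosome 18, 63010213 to 63387716), was at 0.14 ± 0.0382 CPM in HepLPC and 46.0 ± 32.8 CPM in NPC_LPC (log2 fold change -8.29, SE 0.83, edgeR adjusted p = 0.0413). The secreted protein gene Angptl2 (chromosome 2) fell from 94.0 ± 27.1 CPM in NPC_LPC to 0.422 ± 0.36 CPM in HepLPC. Lxn (chromosome 3) fell from 44.1 ± 28.9 to 0.224 ± 0.00223 CPM, Scara3 (chromosome 14) from 129 ± 40.4 to 3.17 ± 0.704 CPM, and Inhba, which encodes a subunit of activin (chromosome 13), from 360 ± 233 to 7.10 ± 3.43 CPM. The interferon-induced genes Oas3 (chromosome 5), Ifi205 and Ifi203 (chromosome 1) were 209-fold, 68.8-fold and 57.9-fold higher in NPC_LPC than in HepLPC. Their NPC_LPC values were 48.3 ± 40.2, 29.3 ± 17.4 and 81.4 ± 40.6 CPM, with replicate 2 above replicate 1 in each. In HepLPC replicates 1 and 2, Oas3 and Lxn had 4 and 4 counts and Ifi205 had 8 and 7. Piezo2 had 3 and 2 counts there and Angptl2 had 3 and 12. Counts this low make the folds imprecise, and the small SDs leave out counting error. Ifi205 and Ifi203 belong to a family of near-identical neighbours, so the split of reads between them is uncertain.

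The number of genes called moved with the test and the libraries. At an unadjusted p under 0.05 the edgeR test had 2704 genes, DESeq2 called 1521 genes and limma-voom 5, and leaving out NPC_LPC replicate 1, NPC_LPC replicate 2, HepLPC replicate 1 or HepLPC replicate 2 gave 377, 107, 0 and 0 genes with edgeR. In each of these settings the 53 genes kept the sign of their fold change. All 53 were called on these same libraries and had groups that do not overlap. Leaving out a library could therefore hardly reverse a sign, and the kept signs are no sign of stability. In 56.4% of all tested genes both libraries of a group lay on the same side of both others, where chance gives 33.3%.

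Camera called 8 of the 25 tested lists, 6 higher and 2 lower in HepLPC, and none was called with an estimated correlation or by fry, where the smallest adjusted p were 0.495 and 0.0884. With an estimated correlation or by fry other lists had smaller p, but with the preset correlation and by median the interferon response list differed most. All 25 of its measured members were lower in HepLPC by fitted value, with a median log2 fold change of -3.88 (camera adjusted p = 5.34e-18; adjusted p = 0.53 with an estimated correlation). Over all genes 1 member passed the edgeR test, and 24 of the 25 passed when adjusted over the list alone. The member that passed was H2-D1, a class I histocompatibility gene, at 97.0 ± 5.76 CPM in HepLPC and 573 ± 96.3 CPM in NPC_LPC (log2 fold change -2.56, SE 0.27, edgeR adjusted p = 0.0419); its reads can be shared with related class I genes. The NPC_LPC libraries were unequal. In 23 of the 25 members replicate 2 exceeded replicate 1, with a median ratio of 2.96 and a largest ratio of 21.01. Isg15, an interferon-induced ubiquitin-like protein, was at 4.83 and 101 CPM in NPC_LPC replicates 1 and 2 and at 0.056 and 0.282 CPM in HepLPC. Ifit1 had no count in HepLPC and was at least 404-fold lower there than in NPC_LPC (67.8 ± 74.1 CPM).

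**Figure D2:**
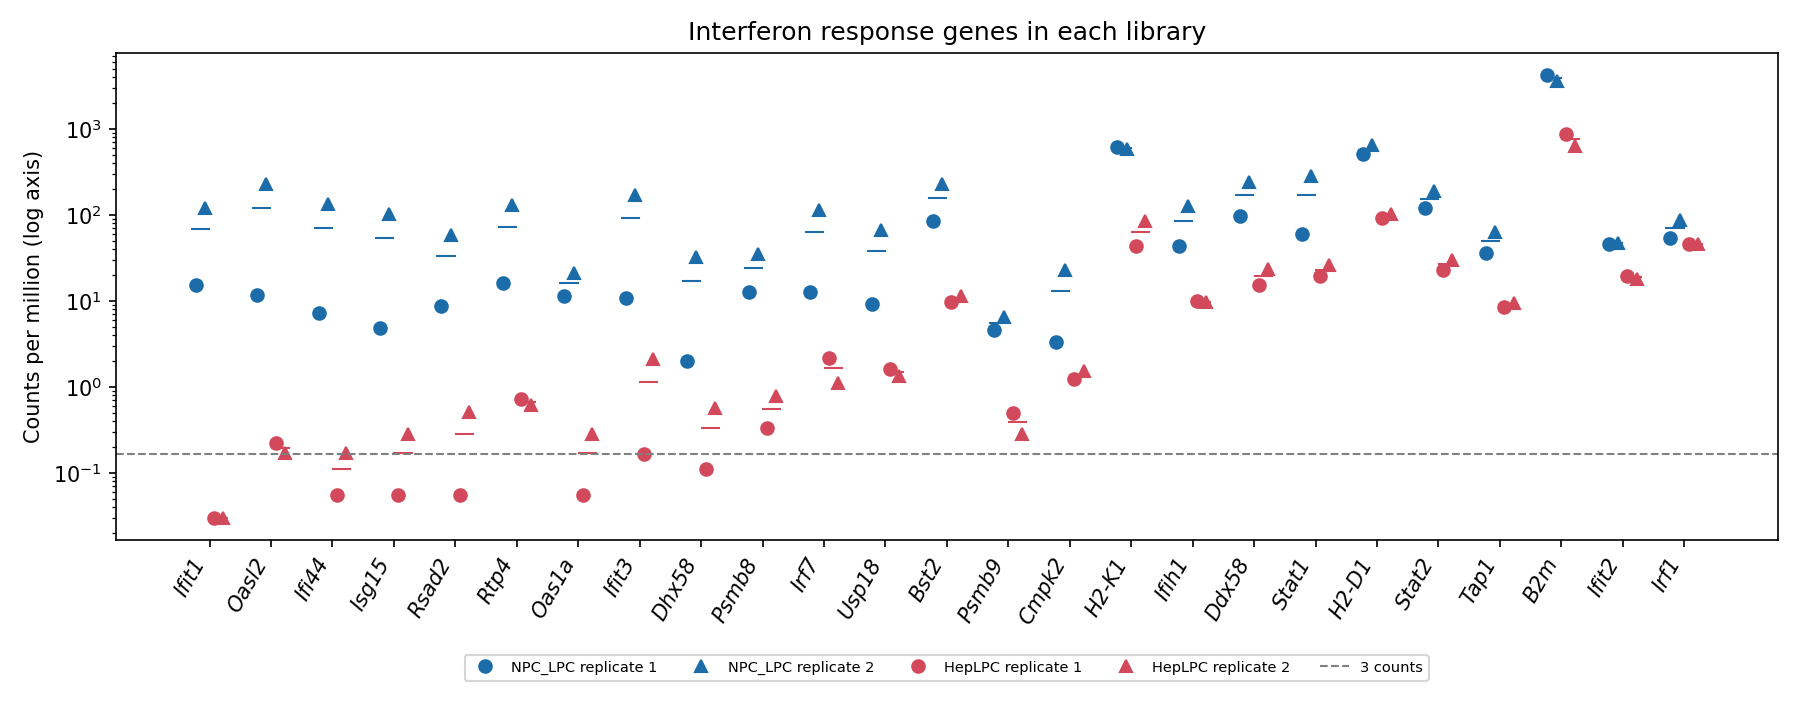
CPM of the 25 interferon response genes (log axis) in each library, ordered by fitted log2 fold change, with circles for replicate 1, triangles for replicate 2, short lines for group means and a dashed line for the highest mean floor of 3 counts; a value of 0 is drawn at 0.03. For every gene both NPC_LPC libraries lie above both HepLPC libraries, and for 23 genes NPC_LPC replicate 2 lies above replicate 1.

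Hepatocyte transcription factors were higher in HepLPC as a list. Of the 15 measured members, 14 had a fold change above 0, the median log2 fold change was 1.38, 1 rose over all genes and 8 rose when adjusted over the list alone (camera adjusted p = 7.84e-06; adjusted p = 0.495 with an estimated correlation). Cebpa, a regulator of hepatocyte differentiation (chromosome 7, 35119293 to 35121928), rose 22.6-fold, from 1.14 ± 0.487 to 25.8 ± 5.48 CPM (log2 fold change 4.50, SE 0.50, edgeR adjusted p = 0.0419). Secreted hepatocyte proteins were also higher as a list, with a median log2 fold change of 1.52 over 10 measured members, 1 that rose over all genes and 4 when adjusted over the list alone (camera adjusted p = 0.00698; adjusted p = 0.495 with an estimated correlation). The list was no longer called without NPC_LPC replicate 2 (camera adjusted p = 0.0505) or without HepLPC replicate 1 (0.0526), in a range of 4.85e-04 to 0.495 over its alternatives. Hpx, the plasma haem carrier, rose from 2.14 ± 0.928 to 45.6 ± 3.54 CPM, 21.3-fold (edgeR adjusted p = 0.0413), while 11 of the 21 members were too low to test. Of 25 genes of hepatocyte metabolism, only 3 were measured well enough to test, and edgeR and DESeq2 called 0 of them. Ass1 was at 193 ± 47.7 CPM and 218 ± 178 CPM, and Glul at 250 ± 140 CPM and 144 ± 79.2 CPM, in HepLPC and NPC_LPC. Of 14 genes of bile acid synthesis and transport 3 were tested, edgeR called 0 over all genes where DESeq2 called 1 higher, and 1 rose when adjusted over the list alone. Without NPC_LPC replicate 1 enough of them passed the filter for camera, which called the list higher in HepLPC (adjusted p = 0.0154; 0.573 without NPC_LPC replicate 2 and 0.251 without HepLPC replicate 2). Abcc2 was at 34.9 ± 18.8 and 13.0 ± 16.6 CPM, and the bile acid receptor Nr1h4 at 24.8 ± 3.85 and 9.11 ± 0.702 CPM.

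The list of foregut, intestine and pancreas genes was higher in HepLPC over the 9 of its 24 members that could be tested, 7 with a fold change above 0 and 2 below, while 12 stayed at or under 3 counts in all libraries. The median log2 fold change of the 9 was 3.0, or 2.75 with the gene absent from NPC_LPC at its lower bound (camera adjusted p = 0.00181; adjusted p = 0.495 with an estimated correlation). The list was no longer called without HepLPC replicate 2 (camera adjusted p = 0.0529), in a range of 1.41e-04 to 0.495 over its alternatives. Of these members 1 rose over all genes and 4 when adjusted over the list alone. Cdx2, an intestinal transcription factor (chromosome 5, 147300900 to 147307249), rose 8.00-fold, from 3.88 ± 0.75 to 31.1 ± 2.54 CPM (log2 fold change 3.0, SE 0.35, edgeR adjusted p = 0.0466).

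Immediate early and handling stress genes were higher in HepLPC, all 20 members by fitted value, with a median log2 fold change of 1.55 (camera adjusted p = 7.45e-10; adjusted p = 0.495 with an estimated correlation). Over all genes 2 rose, and 14 when adjusted over the list alone. Zfp36, which encodes a protein that destabilises messenger RNA, rose from 35.1 ± 3.72 to 344 ± 41.9 CPM, and the stress-induced transcription factor Atf3 from 8.87 ± 0.204 to 67.3 ± 7.44 CPM (edgeR adjusted p = 0.0304 and 0.0413). Cell cycle genes were higher in HepLPC for 34 of 35 members, with a median log2 fold change of 0.77 and no member past the edgeR test over all genes or adjusted over the list alone, where DESeq2 called 4 members (camera adjusted p = 2.89e-07; adjusted p = 0.869 with an estimated correlation). The libraries of a group were far apart. The list summed to 6945 and 4554 CPM in HepLPC replicates 1 and 2 and to 2595 and 4367 CPM in those of NPC_LPC, so the replicates numbered 2 were close. Top2a was at 662 and 385 CPM in HepLPC and at 206 and 457 CPM in NPC_LPC, in the same order.

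The epithelial junction list was higher in HepLPC and the mesenchymal list lower. Of 19 junction genes, 15 had a fold change above 0, with a median log2 fold change of 0.87, edgeR called 0 over all genes where DESeq2 called 5 higher and 1 lower, and 3 rose when adjusted over the list alone (camera adjusted p = 0.00698; adjusted p = 0.53 with an estimated correlation). The list was no longer called without HepLPC replicate 2 (camera adjusted p = 0.105), in a range of 9.66e-04 to 0.53 over its alternatives. The simple-epithelium keratins Krt8 and Krt18 were at 3161 ± 1229 and 2761 ± 1356 CPM in HepLPC and at 1104 ± 575 and 1172 ± 560 CPM in NPC_LPC. Both genes lie on chromosome 15, whose genes as a whole were higher in HepLPC (below). Of 19 mesenchymal genes, 15 had a fold change below 0, with a median of -0.72, and 1 fell over all genes and 6 when adjusted over the list alone (camera adjusted p = 7.87e-04; adjusted p = 0.495 with an estimated correlation). The matrix glycoprotein gene Tnc (chromosome 4, 63959785 to 64047015) fell from 1920 ± 190 to 68.7 ± 20.1 CPM (log2 fold change -4.80, SE 0.36, edgeR adjusted p = 0.0265). The markers of stellate cells and myofibroblasts (below), many of them mesenchymal genes too, summed to 615 and 753 CPM in HepLPC replicates 1 and 2 and to 2854 and 3828 CPM in those of NPC_LPC, most of it Fbln2. Vim, in the mesenchymal list, had a log2 fold change of 0.29 (SE 0.28) and did not pass edgeR or DESeq2.

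**Figure D3:**
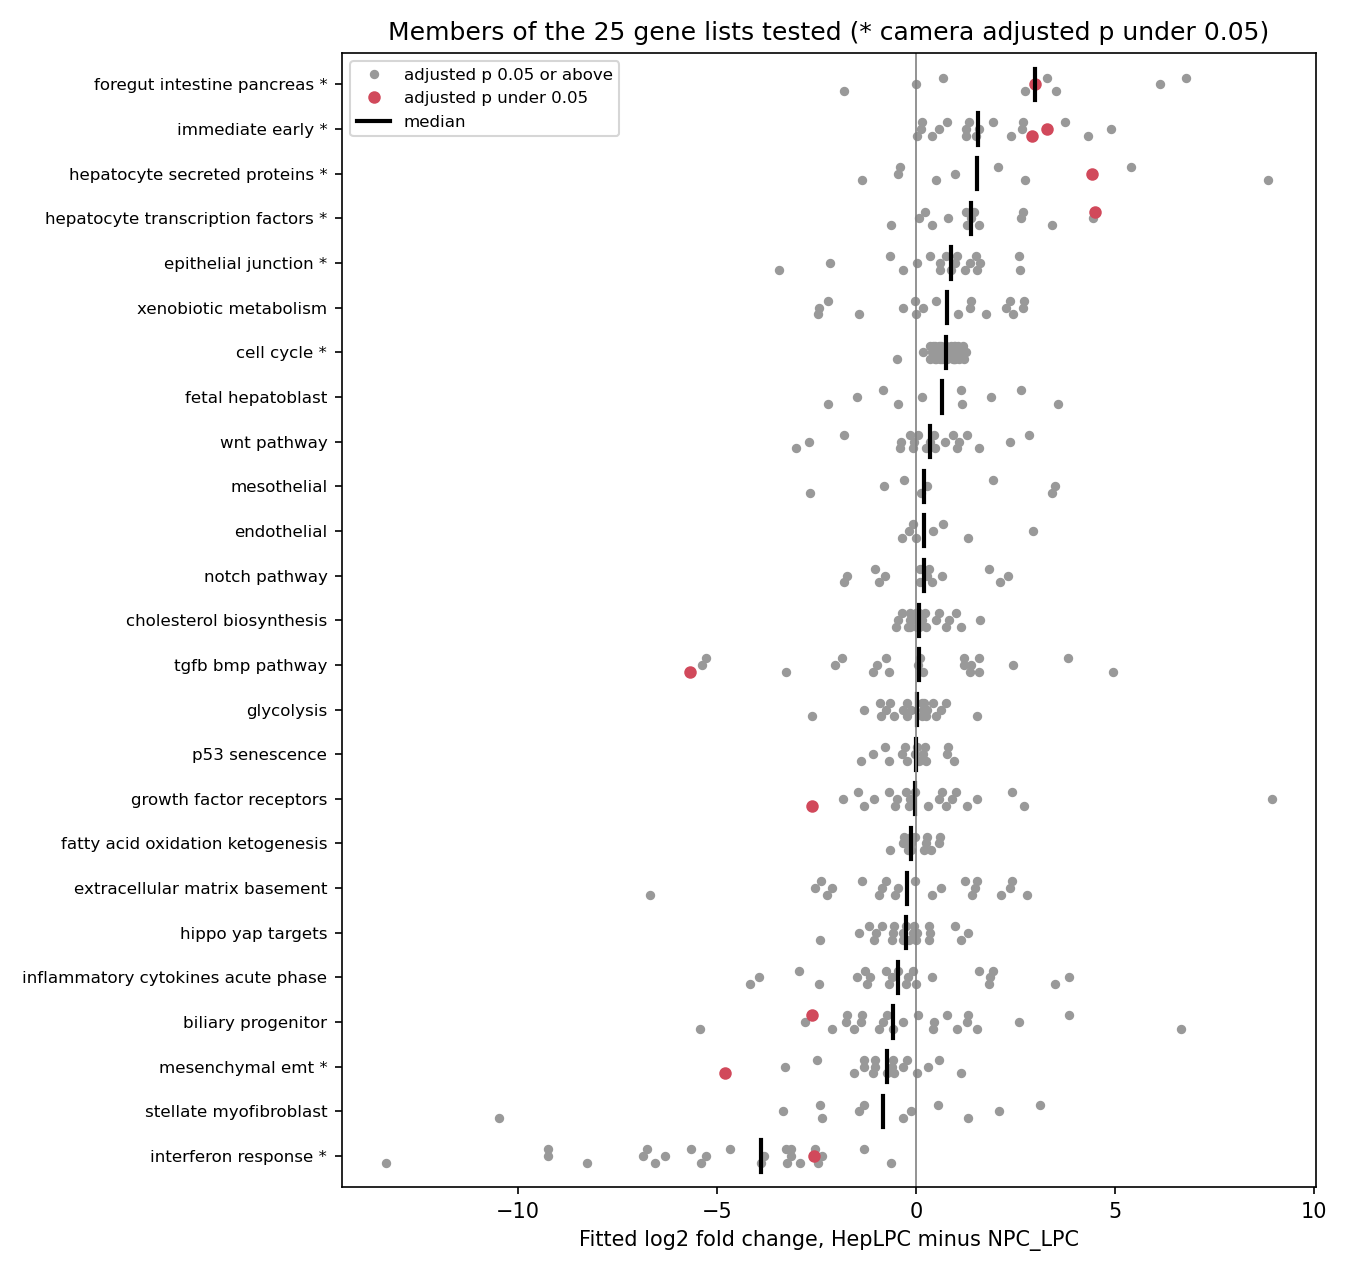
Fitted log2 fold changes (HepLPC minus NPC_LPC) of the measured members of each of the 25 tested gene lists, 1 point per gene, with members past the edgeR threshold in red and the list median as a black line. Fitted values of genes with no count in a group depend on the prior count. The interferon response list has its median at -3.88, and lists marked with an asterisk were called by camera with the preset correlation.

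Biliary and progenitor markers went both ways and were not called as a list (median log2 fold change -0.59 over 25 members, camera adjusted p = 0.37). Fgfr2, a receptor for fibroblast growth factors (chromosome 7), fell 6.10-fold in HepLPC, from 72.5 ± 10.4 to 11.9 ± 2.18 CPM (edgeR adjusted p = 0.0436), and 4 members rose and 4 fell when adjusted over the list alone. Fetal hepatoblast markers (median 0.65, 10 members) were not called as a list by camera (adjusted p = 0.521), and edgeR called 0 members where DESeq2 called 3 higher. Its 2 most abundant members, Peg3 and Hmga2, were at 862 ± 578 and 328 ± 99.8 CPM in HepLPC and at 2400 ± 1042 and 586 ± 290 CPM in NPC_LPC. Xenobiotic metabolism (median 0.77, 18 members, 0 called by edgeR, 2 called higher and 4 lower by DESeq2) was not called by camera (adjusted p = 0.263), but was called higher in HepLPC without NPC_LPC replicate 1, at an adjusted p of 1.78e-04, in a range up to 0.932 over its alternatives. Ephx1 was at 410 ± 17.2 and 416 ± 209 CPM and Aldh1a1 at 252 ± 152 and 222 ± 283 CPM in HepLPC and NPC_LPC.

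Lists of markers of other cell types that a liver preparation could hold had no gene past the edgeR test over all genes, and several of their markers were abundant. For stellate cells and myofibroblasts the median log2 fold change was -0.82 over 12 measured members (camera adjusted p = 0.328, and from 0.00136 without NPC_LPC replicate 1 to 0.777 over its alternatives), with 1 that rose and 4 that fell when adjusted over the list alone, and DESeq2 called 1 member higher and 3 lower over all genes. Fbln2 was at 607 ± 103 and 3124 ± 772 CPM and Col5a1 at 18.1 ± 3.82 and 95.3 ± 59.0 CPM in HepLPC and NPC_LPC. Mesothelial (median 0.21, 8 members, camera adjusted p = 0.497, and from 0.0443 without NPC_LPC replicate 1 to 0.932 over its alternatives) and endothelial markers (median 0.21, 8 members, camera adjusted p = 0.37) had 0 members called by edgeR over all genes, where DESeq2 called 1 higher in each list, and 1 endothelial gene rose when adjusted over the list alone. Msln was at 492 ± 415 and 403 ± 242 CPM, C3 at 265 ± 298 and 461 ± 356 CPM, Flt4 at 94.9 ± 11.9 and 101 ± 9.35 CPM and Egfl7 at 8.80 ± 2.33 and 6.57 ± 1.84 CPM in HepLPC and NPC_LPC. Of 20 macrophage and Kupffer cell markers 13 stayed at or under 3 counts in all libraries, and edgeR and DESeq2 called 0 of the 3 tested. Cd14 was at 63.1 ± 36.7 and 102 ± 72.1 CPM and Cd68 at 17.5 ± 5.92 and 50.1 ± 42.0 CPM, and both are also expressed outside macrophages. Lymphocyte markers summed to at most 2.87 CPM in a library, with Cd79a at 1.32 ± 0.528 and 0.129 ± 0.0275 CPM and Lck at 0.867 ± 0.0309 and 0.286 ± 0.0161 CPM in HepLPC and NPC_LPC, and 1 of 2 tested members passed when adjusted over the list alone. Erythroid markers summed to at most 0.83 CPM, with Slc4a1 at or below 0.778 CPM in any library.

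The remaining pathway lists were not called by camera. Medians of log2 fold changes and camera adjusted p were -0.0053 and 0.864 for p53 and senescence genes (16 members), -0.26 and 0.524 for YAP targets (23 members), 0.19 and 0.864 for the Notch pathway (14 members) and 0.34 and 0.524 for the Wnt pathway (21 members). They were 0.073 and 0.864 for the TGF-beta and BMP pathway (22 members), -0.013 and 0.864 for growth factor receptors (23 members) and -0.45 and 0.799 for inflammatory cytokines and acute phase genes (23 members). For metabolism and matrix they were 0.074 and 0.263 for cholesterol synthesis (23 members), -0.12 and 0.864 for fatty acid oxidation (15 members), 0.022 and 0.864 for glycolysis (22 members) and -0.23 and 0.971 for extracellular matrix and basement membrane genes (22 members). In 5 of these lists, TGF-beta and BMP, growth factor receptors, fatty acid oxidation, glycolysis and extracellular matrix, the median, the mean and the camera direction did not share a sign. Leaving out NPC_LPC replicate 1 brought YAP targets to an adjusted p of 0.0304, and leaving out HepLPC replicate 1 brought cholesterol synthesis to 0.00975, where both lists reached 0.932 over their alternatives. Inhba fell within the TGF-beta list and Fgfr2 within the receptor list. Adjusted over the list alone, 6 rose and 8 fell in the TGF-beta list, 3 and 3 in the Notch list, 3 and 3 among receptors, 5 and 5 in the matrix list and 2 and 2 among inflammatory genes, and 1 Wnt gene and 1 glycolysis gene fell and 1 cholesterol gene rose.

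Values of the most abundant members of the lists without a gene called by edgeR follow, HepLPC before NPC_LPC, with some of these members not used here. Ccng1 was at 1237 ± 60.4 and 1450 ± 148 CPM. Ctgf was at 981 ± 484 and 2042 ± 1280 CPM, and Myof at 1319 ± 130 and 1058 ± 388 CPM. Notch1 was at 216 ± 82.7 and 139 ± 60.9 CPM, and its ligand Jag1 at 80.3 ± 20.8 and 269 ± 110 CPM. The Wnt pathway genes Rnf43 and Axin2 were at 114 ± 34.5 and 38.0 ± 40.2 CPM and at 50.5 ± 2.56 and 39.9 ± 7.86 CPM. The cytokine Cxcl1 was at 1007 ± 45.4 and 762 ± 209 CPM, and the iron-binding protein Lcn2 at 67.4 ± 72.6 and 1205 ± 751 CPM (edgeR adjusted p = 0.115). Srebf2, on chromosome 15, was at 323 ± 123 and 160 ± 1.31 CPM. Hadha was at 169 ± 39.1 and 142 ± 3.08 CPM, Pkm at 3663 ± 276 and 3066 ± 261 CPM and Eno1 at 1180 ± 372 and 1277 ± 139 CPM. Col4a1 was at 361 ± 123 and 1549 ± 783 CPM, and Timp2 at 591 ± 113 and 853 ± 33.6 CPM.

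HepLPC replicate 2 differed from the other libraries in genes of the Y chromosome. Ddx3y was at 84.8 and 70.9 CPM in NPC_LPC replicates 1 and 2, at 57.3 CPM in HepLPC replicate 1 and at 0.056 CPM, a count of 1, in HepLPC replicate 2. Eif2s3y was at 97.1, 51.9, 61.3 and 0.056 CPM in the same order. The 4 Y-linked genes of the list together had 3 counts in HepLPC replicate 2 and between 3404 and 5316 counts in the other libraries. The labels used here do not state the sex of the mice.

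Genes of whole chromosomes also differed between libraries, a comparison chosen after seeing the data. Over 8824 genes, the median log2 ratio of HepLPC over NPC_LPC was -0.59 for the 525 genes of chromosome 4, -0.47 for the 300 genes of chromosome 14 and 0.65 for the 373 genes of chromosome 15 (permutation test over bins, adjusted p = 1.5e-04, 2.4e-04 and 1.5e-04). The chromosome 14 value came mainly from HepLPC replicate 1, with a median of -0.76 against NPC_LPC, where replicate 2 alone had -0.16. The medians of HepLPC replicates 1 and 2 were -0.76 and -0.41 on chromosome 4 and 0.54 and 0.79 on chromosome 15. On chromosome 15, 82.8% of the genes were higher in HepLPC, and on chromosome 4, 86.1% were lower. Libraries of the same origin differed as well, by similar sizes. The p-values are over bins within a comparison, so they do not set origin apart from variation between libraries. HepLPC replicate 2 exceeded replicate 1 by a median of 0.67 on chromosome 19, 0.60 on chromosome 14 and 0.35 on chromosome 4, and NPC_LPC replicate 2 minus replicate 1 was -0.52 on chromosome 19 (permutation test, adjusted p = 1.5e-04, 3e-04, 0.0347 and 1.5e-04). The other 53 pairs of chromosome and comparison had adjusted p above 0.05. With each chromosome's median removed per library, edgeR called 70 genes, 51 of them among the 53.

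**Figure D4:**
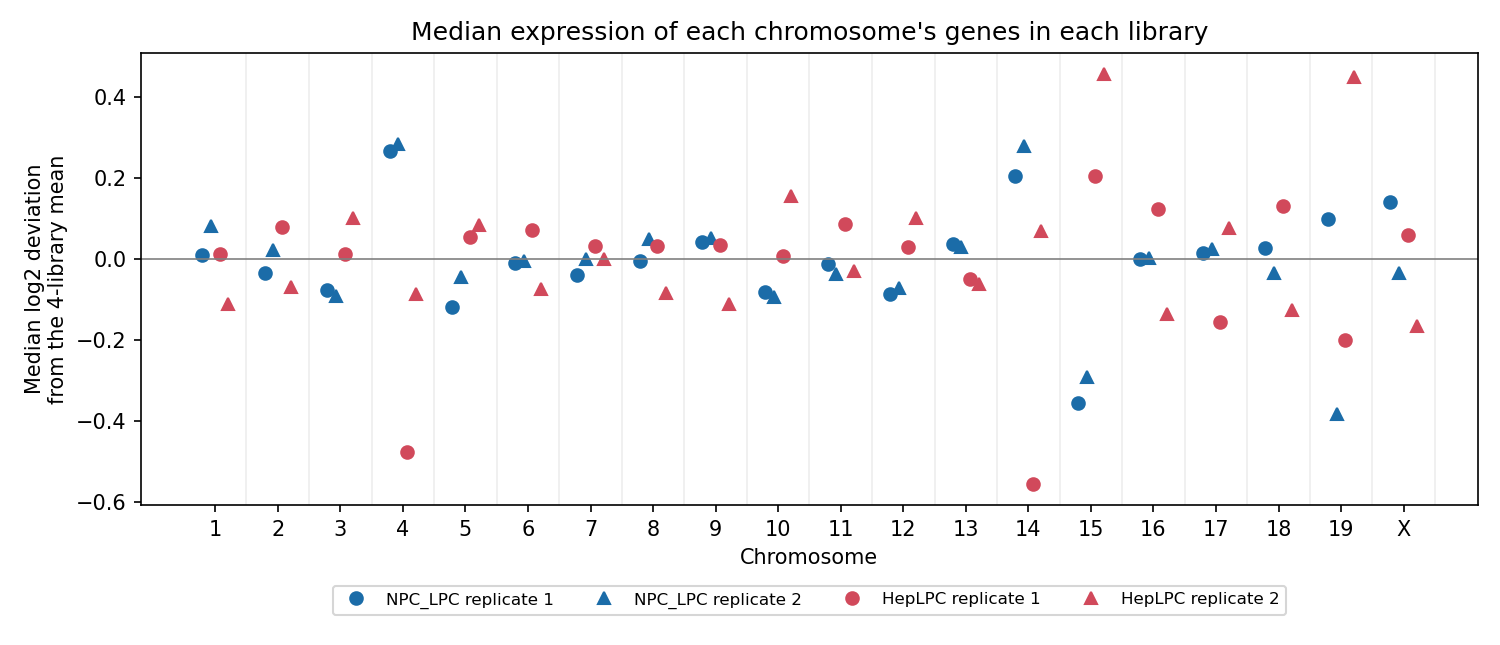
Median log2 deviation of each library from the mean of the 4 libraries for the genes of each chromosome (8824 genes), with circles for replicate 1 and triangles for replicate 2. Both NPC_LPC libraries lie at -0.36 and -0.29 on chromosome 15 and both HepLPC libraries at 0.21 and 0.46, and on chromosome 19 replicates of the same origin lie apart.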

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

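The count of 53 genes that differed between HepLPC and NPC_LPC (28 higher, 25 lower, 53 at least 2-fold) changed by more than 1.5 times in 13 of 21 alternatives, 1 of which, limma on log2(FPKM + 1), was chosen after seeing the data. In all alternatives no called gene changed sign, which their selection on these same libraries made likely. With no filter on low counts edgeR called 593 genes (259 higher, 334 lower, 593 at least 2-fold). DESeq2 called 1521 (702, 819 and 1377) and limma-voom 5 (2, 3 and 5). FPKM gave 0 with no filter, where limma had 2820 genes at an unadjusted p under 0.05, 114 with a mean of at least 1 (60, 54 and 114), 129 after quantile normalization (68, 61 and 129) and 111 with a pseudocount of 1 (59, 52 and 111). A threshold of 0.01 gave 0. The replicate block in edgeR gave 136 (49, 87 and 136, 50 of them among the 53). Same-numbered replicates did not deviate together across genes as a whole (r = -0.017). That value cannot exclude a shared donor, day or batch, so whether replicates are paired stays open. Leaving out each library gave from 0 to 377 genes (0 to 156 higher, 0 to 221 lower, 0 to 377 at least 2-fold), where the lone library is assumed to vary like the other group. Leaving out HepLPC replicate 1 or 2 gave 0 in edgeR, with 2065 and 2258 genes at an unadjusted p under 0.05. The cause of these changes was not tested. The other 8 alternatives gave from 38 to 70 genes.

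Camera called 8 lists, 0 with an estimated correlation (0 at an unadjusted p under 0.05), 0 by fry (6 at an unadjusted p under 0.05), 8 with the replicate block and from 6 to 13 without each library, the highest without NPC_LPC replicate 1. Mean r within groups exceeded that between groups by 0.077, by 0.032 over all genes above 0 and by 0.052 with Spearman's correlation. Of 1405 alternative values of 75 named genes, 1247 kept their side of the threshold, 116 lost and 42 gained the call and 0 called values changed sign; 43 changes of sign were of genes not called in either setting.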

Other observations

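The tests of explanations for the chromosome, Y-linked and interferon patterns were chosen only after the results were seen, while the edgeR test and the gene lists were planned. The genes in this and the next paragraph were picked after their values were seen, so they describe no tested theme. Several genes that rose in HepLPC are among those expressed in gut epithelium, with varied functions. Besides Cdhr5, Lgals2 and Gcnt3, these were Cobl, an actin nucleator (59.1 ± 11.6 CPM against 2.11 ± 0.0314, edgeR adjusted p = 0.0265), Bco1, which cleaves beta-carotene (32.1 ± 2.30 against 1.44 ± 0.411, adjusted p = 0.0413), and Plac8 (52.0 ± 21.8 against 2.71 ± 0.651, adjusted p = 0.0419). The epithelial cytokine receptor gene Il22ra1 rose from 19.6 ± 0.318 to 129 ± 21.8 CPM (edgeR adjusted p = 0.0413). The brush border gene Vil1 was at 14.5 ± 5.40 and 2.14 ± 2.86 CPM and did not pass (edgeR adjusted p = 0.279).

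Some genes with roles in contraction or matrix fell in HepLPC, though the fixed list of extracellular matrix genes was not called (camera adjusted p = 0.971). Tns1, which links actin to integrins, fell from 996 ± 19.4 to 31.9 ± 4.71 CPM, the collagen gene Col12a1 from 322 ± 197 to 8.40 ± 0.163, Tnnt2, a troponin, from 155 ± 48.6 to 15.01 ± 2.74, and Ppp1r12b, a myosin phosphatase subunit, from 90.7 ± 14.97 to 9.05 ± 3.79 (edgeR adjusted p between 0.0265 and 0.0466). Plasma protein genes did not move together. Gc, the vitamin D-binding protein of hepatocytes, fell from 620 ± 12.9 CPM in NPC_LPC to 30.4 ± 8.44 in HepLPC (edgeR adjusted p = 0.0265), while Hpx rose and Rbp4 was at 73.7 ± 27.2 and 490 ± 3.15 CPM in NPC_LPC and HepLPC (adjusted p = 0.0504).

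The medians of chromosomes 4, 14, 15 and 19 differed between libraries by 0.4 or more on the log2 scale in 6 pairs of chromosome and comparison. GC content and gene length as the whole cause are argued against, since after a fit on both the smallest of these medians still had a size of 0.43 against 0.47 before, and of 0.40 in FPKM. Local gene clusters were not tested independently. The pairs were chosen by a chromosome median of 0.4 or more in size, which makes bins of the same sign likely. All 36 bins along these chromosomes had the sign of their chromosome, and 35 of the 36 had a size of 0.3 or more. On chromosome 14 the even difference by origin belongs to HepLPC replicate 1 (bins of -0.89 to -0.70), while bins of replicate 2 ran from -0.36 to 0.10. The difference of HepLPC replicate 2 minus replicate 1 was less even. Its bins ran from 0.39 to 0.87 on chromosome 14 and from 0.45 to 0.87 on chromosome 19. An even shift is what a different number of chromosome copies in the cultured cells may give. As a scale, 3 copies in place of 2 correspond to 0.58. A difference in copy number remains a hypothesis, found and tested on the same data with no DNA measurement. Origin, donor mouse and culture history cannot be separated in it.

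The Y-linked genes were nearly absent from HepLPC replicate 2. A library of the other group under a wrong label is argued against, since its r with HepLPC replicate 1 was 0.947 and at most 0.873 with an NPC_LPC library; an outside sample of the same kind stays open. A female donor mouse may account for it. Of 6 genes that escape X inactivation, 4 lay above the median of X genes in replicate 2 against replicate 1. Ddx3x and Utp14a lay close below it, at log2 ratios of -0.35 and -0.33, so both were lower in replicate 2 than in replicate 1. The median of the 6 was 0.46 against -0.24 for X genes, at percentile 99.95 of 10000 random sets of X genes. That median goes with a second active copy of these genes, but the lower values of Ddx3x and Utp14a do not. The percentile also does not measure variation between libraries. Eif2s3x and Pbdc1 were already at 285 and 76.4 CPM in HepLPC replicate 1, against at most 194 and 45.7 CPM in NPC_LPC. Ddx3x, Utp14a and Kdm5c were also higher there, at 904, 89.0 and 150 CPM against at most 552, 70.7 and 139 CPM. Kdm6a was not higher there than in NPC_LPC replicate 1. Xist, the remaining gene of the fixed sex list, had no row in the deposited values. Loss of the Y chromosome in male cells could account for the near absence of Y-linked transcripts as well. The mean of the escape genes that lack a Y-linked copy, Utp14a and Pbdc1, was 0.52 above the median of X genes. But the genes lay at -0.092 and 1.13 against that median. A female donor and loss of the Y chromosome cannot be told apart here, because these genes did not move together and a rise of those with a lost Y-linked copy was not tested.

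The interferon response list was lower in HepLPC and uneven within NPC_LPC. RNA from immune cells is argued against, since 6 abundant leukocyte transcripts from the fixed list of macrophage markers (Ptprc, Laptm5, Tyrobp, Fcer1g, Cd52 and Lyz2) together reached at most 0.0213% of the excess CPM of the list in an NPC_LPC library. The whole macrophage list of 20 genes reached 4.81% and 1.18% in NPC_LPC replicates 1 and 2, nearly all of it Cd14 and Cd68, which HepLPC also expressed; its other 18 genes summed to 2.91 and 1.54 CPM there and to 3.72 and 2.14 CPM in HepLPC replicates 1 and 2. NPC_LPC replicate 2 alone is argued against, since all 25 members were higher in NPC_LPC replicate 1 than in both HepLPC libraries, and so are the chromosome shifts, since with their medians removed the median log2 fold change was still -3.84. A difference by cell origin stays open as a hypothesis, along with donor line and culture, and Ifnb1, Ifng, Ifnl2 and Ifnl3 had 0 counts in all 4 libraries, so the values may reflect interferon made earlier or elsewhere, or signalling without it.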
